A study of Mus musculus with 14 samples.

How the data were processed

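The series holds bulk ATAC-seq of mouse long-term haematopoietic stem cells in 14 libraries from 3 groups: young (n = 4), aged (n = 5) and aged treated with the RhoA inhibitor Rhosin (Ri, 100 µM, n = 5). Per the labels' protocols, sorted cells were kept for 16 h in HBSS with 10% FBS at 37 °C, 3% oxygen and 5% carbon dioxide, and lysed with 0.15% NP-40. The labels give 3 sequencing batches. Batch 1 holds young 1, aged 1 and 2 and aged Ri 1 and 2, batch 2 holds young 2 and 3, aged 3 and 4 and aged Ri 3 and 4, and batch 3 holds young 4, aged 5 and aged Ri 5.

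The deposited count matrix gives raw counts per consensus peak and library, in 57289 peaks of 700 bp on mm10. Per the submitters' processing notes, SAMtools 1.14, R 4.2.0 and featureCounts (no version given) were used. The notes do not state the aligner, the peak caller, the handling of duplicates or a shift for Tn5. The values were checked to be whole numbers, and no deposited normalization was used. Totals ran from 765533 (young 3) to 3176246 (aged Ri 3) counts, with a median of 7 (young 3) to 30 (aged Ri 3) counts per peak. At these depths single peaks carry large counting error, and gene ends, which collect more counts, carry less.

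Differential accessibility was tested with R 4.3.3 and edgeR 4.0.16 on all 14 libraries (filterByExpr by group, TMM, robust quasi-likelihood fit, group and sequencing batch as terms), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were taken from the log2 fold change and the quasi-likelihood F statistic. CPM (counts scaled to a common library size) used the TMM scaling, and log values a prior count of 2. Peaks were scaled over all peaks kept, and gene ends over gene-end counts alone. A shift of counts to or from gene ends is therefore scaled away in the gene-end tests. The filter kept 56235 peaks. The 3 comparisons were aged against young, aged Ri against aged, and aged Ri against young. Group means of CPM are not adjusted for batch, so a fold from the model can differ from their ratio.

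Gene symbols and spans came from the RefSeq annotation of GRCm38.p6, the assembly called mm10, with 21887 protein-coding genes. It gives no strand, so start sites could not be placed and the planned promoter test was run on gene ends. For each gene, the peaks overlapping 1 kb either side of each annotated end were summed, and the end with more counts over all libraries was used. This gave 13263 genes, 1764 of them with peaks at both ends, and 1622 of the 12675 peaks used were shared by 2 or more genes. A gene end can therefore be the 3' end. Single peaks were named by the nearest protein-coding gene span within 50 kb, which 50693 peaks had. By class, 13788 peaks lay at gene ends, 23092 in gene spans and 20409 between genes.

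The choices of test, comparisons, gene lists and alternatives were fixed before the data were examined. So was the rule for the genes named: called peaks with a mean count of at least 20 that kept their direction in each of the 3 batches, the 12 with the largest and the 12 with the smallest log2 fold change per comparison and at most 1 per gene; 5 gene ends each way by the same rule; up to 4 called members of each gene list by smallest p; and Rhoa, Klf4, Kit, Procr, Vwf and Selp. The report names part of these.

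The 16 gene lists (403 of 405 symbols matched) were tested with camera in limma 3.58.1 on voom values of gene ends, with a preset correlation between genes of 0.01, and again with the estimated correlation. These 16 lists were adjusted together within a comparison, and the 4 lists added later were adjusted apart, among themselves. Another 4 lists (NRF2 targets, aryl hydrocarbon receptor targets, integrated stress response, heat shock) were added after the response to Ri was seen and leave out Cyp1b1 and Nqo1, which prompted 2 of them. Shares of counts, library totals and a per-library ageing score were compared by 2-sided exact permutation in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Figures were drawn with matplotlib 3.10.9. The score of a library was the mean batch-centred log2 CPM of peaks higher in aged cells less that of peaks lower, called without that library. For the reversal question, 50 sets of all 14 libraries were drawn from fitted means with the aged Ri libraries at the aged mean for the correlation, and 10 further sets for the share moved back, with the calls fitted again in each. The planned simulation kept the aged libraries as they were, but the fitted aged mean carries their noise, so they were redrawn too. The aged libraries were split between the 2 comparisons in 10 ways, and, as an addition, with each aged Ri library kept with the aged library of its number. The young libraries were split in 6 ways, and aged Ri libraries were drawn at the young mean in 10 sets.

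The labels number the replicates alike in each group, so the numbers were checked for pairing on the 25903 peaks with a mean count of at least 20. Aged and aged Ri libraries of the same number deviated together from their group means in each of 5 pairs (r from 0.137 to 0.645), and in 4 of 5 the own number gave the highest r. The labels do not state that a number marks a shared animal, so the pairing comes from the data. Young libraries did not pair with aged (r from -0.278 to 0.0700) or aged Ri ones (-0.201 to 0.0732).

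Replicates within a group correlated with r from 0.769 to 0.901. Libraries of different groups gave r from 0.596 to 0.906, so the 2 ranges overlap. The pipeline was tested on simulated data with 50 changed features per fold size. At 2-fold, 20% (aged against young), 32% (aged Ri against aged) and 24% (aged Ri against young) of changed peaks among 56235 were recovered, and at 4-fold 78%, 92% and 82%. Of changed gene ends among 13239, 70%, 86% and 82% were recovered at 2-fold. Each simulated comparison gave 3 to 12 false calls. A low count of calls therefore does not show that accessibility was equal.

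Alternatives covered DESeq2 1.42.0 (size factors and Wald test), library size alone, cyclic loess offsets, other filters, limma voom with quality weights, no batch term, the compared groups alone, a replicate block, gene-end windows of 500 bp and 2 kb, and each library left out in turn. After the data were seen, 2 were added for the tests across peaks and gene ends: leaving out young 1 and young 3, and the gene-end share of counts as a covariate. Motif scores, GC content and repeat classes were left out, since no genome sequence was used here.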

Results

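Chromatin accessibility was profiled by bulk ATAC-seq, which reads where the transposase Tn5 can cut open chromatin, in mouse long-term haematopoietic stem cells (LT-HSCs, Lin- Sca1+ cKit+ CD34- Flt3-). The 14 libraries fell into 3 groups of C57BL/6 cells: young (10 to 16 weeks, n = 4), aged (over 80 weeks, n = 5) and aged treated with Rhosin (n = 5). Rhosin, called Ri here, is a small molecule that blocks the activation of the GTPase RhoA, a regulator of the actin cytoskeleton, and was used at 100 µM. All cells were kept for 16 h at 37 °C and 3% oxygen, and the libraries were sequenced in 3 batches, each holding all 3 groups. Libraries held 765533 (young 3) to 3176246 (aged Ri 3) counts in 57289 peaks of 700 bp. Totals averaged 1674901 ± 690400 (SD, n = 4) in young, 1864900 ± 656562 (SD, n = 5) in aged and 2278388 ± 827453 (SD, n = 5) in aged Ri libraries. They did not differ detectably between aged and young (2-sided exact permutation test over all libraries, p = 0.698; within batches, p = 0.667), between aged Ri and aged (p = 0.365 by the same exact permutation; within batches, p = 0.139) or between aged Ri and young (exact permutation p = 0.270; within batches, p = 0.278). The replicates are biological per the series description, and the number of animals behind each is not stated. Positions are on mm10.

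The first comparison asked what ageing changes in LT-HSC chromatin. Aged cells gained accessibility at Nupr1, a stress-induced chromatin protein, at Cavin2, a caveola coat protein, and at Wwtr1, which encodes the mechanosensitive co-activator TAZ. At the annotated end of Nupr1 (chromosome 7, 126625242 to 126625941), the signal rose from 7.63 ± 3.90 (SD, n = 4) to 50.9 ± 19.5 (SD, n = 5) CPM, 5.85-fold (log2 2.55 ± 0.29 SE; edgeR adjusted p = 6.24e-07). Cavin2 (chromosome 1, 51288922 to 51289621) rose 4.62-fold (log2 2.21 ± 0.25 SE; edgeR adjusted p = 6.24e-07) and Wwtr1 (chromosome 3, 57575629 to 57576328) 3.23-fold (log2 1.69 ± 0.22 SE; edgeR adjusted p = 1.83e-05). The chromatin gained in aged cells lay mostly away from gene ends, within gene spans and between genes.

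A gene end here is the annotated end of a gene whose peaks within 1 kb held more counts, since the annotation gave no strand. Of 13239 gene ends tested in aged against young cells, 278 changed at an edgeR adjusted p under 0.05, 247 of them upward and 31 downward, and 2333 had an unadjusted p under 0.05. Gene ends were scaled over gene-end counts alone, so the lower share of counts at gene ends in aged libraries is scaled away. Scaled over all peaks, the same peaks gained less: log2 2.33 at Nupr1, 1.94 at Cavin2 and 1.51 at Wwtr1. Among the strongest gains were Arap3 (5.79-fold), a GTPase-activating protein, Slamf8 (4.59-fold), a myeloid surface receptor, and Gp2 (4.45-fold), a glycoprotein of secretory granules. Nupr1, Cavin2, Wwtr1, Arap3 and Gp2 kept their calls under every alternative setting and every left-out library. Gpr183, an oxysterol receptor, rose 3.50-fold, Plscr1, a phospholipid scramblase, 2.05-fold and Amotl2, a regulator of YAP, 2.24-fold. These 3 calls ended without young 1 (edgeR adjusted p = 0.0839, 0.0788 and 0.0606). Vwf, which encodes von Willebrand factor and marks platelet-biased stem cells, rose 2.85-fold (edgeR adjusted p = 0.0133), and its call ended without young 1 (0.151), young 2 (0.0652) or aged 3 (0.0972). Gp1ba, a platelet receptor for that factor, rose 2.97-fold, and its call ended without young 3 or aged 3 (edgeR adjusted p from 0.0539 to 0.0638). Among the losses, Lmnb1, which encodes lamin B1 of the nuclear envelope, fell by 0.54 ± 0.15 SE on the log2 scale (edgeR adjusted p = 0.0429), and its call ended without any 1 of young 1, young 2, young 3, aged 1, aged 2 or aged 3 (0.0638 to 0.249). Pxn, which encodes the focal-adhesion adaptor paxillin, fell by 1.51 ± 0.37 SE (edgeR adjusted p = 0.0334), and its call ended without any 1 of young 1, young 3, aged 1, aged 2 or aged 3 (0.0761 to 0.382). Kit (log2 0.05, edgeR adjusted p = 0.901), Klf4 (log2 -0.29, edgeR adjusted p = 0.326), Procr (log2 0.54, edgeR adjusted p = 0.248), Selp (log2 0.82, edgeR adjusted p = 0.316) and Rhoa (log2 -0.12, edgeR adjusted p = 0.720) did not pass at their gene ends. The number of gene ends called was 30 without young 1, 107 without young 2, 110 without young 3, 658 without young 4, 136 without aged 1, 102 without aged 2, 63 without aged 3 and 662 without aged 5.

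**Figure D1:**
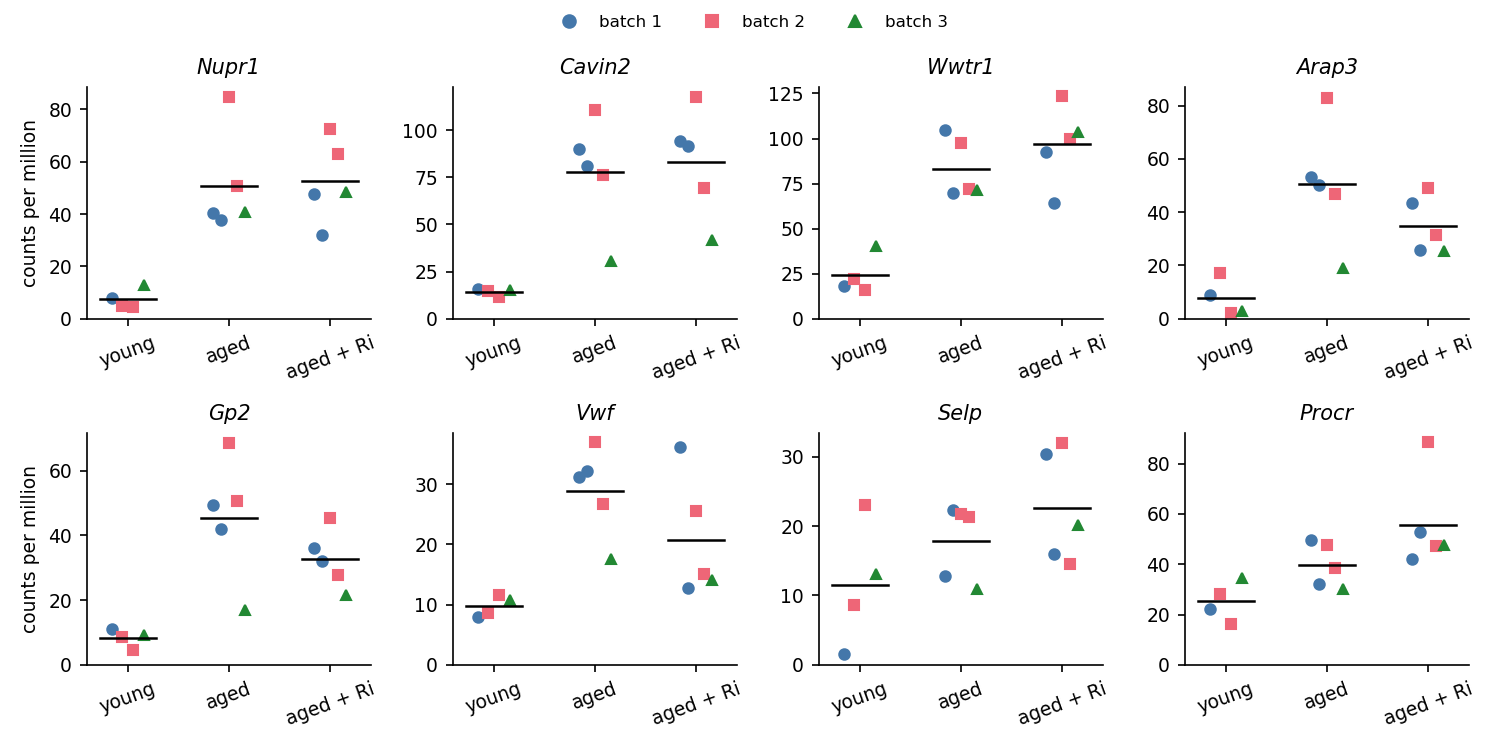
CPM (TMM-scaled, linear axis) at the gene ends of 8 genes in each library, with dots coloured by sequencing batch and a black line at each group mean. Nupr1 averaged 7.63 in young, 50.9 in aged and 52.7 in aged Ri libraries.

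Of 56235 peaks tested, 3214 changed in aged cells, 2504 upward and 710 downward, by a median of 2.42-fold. With offsets that removed trends against mean accessibility, the split was 2320 higher and 1166 lower, a smaller excess of gains. A peak inside Rftn1 (chromosome 17, 50161216 to 50161915), which encodes a lipid-raft protein, rose 9.50-fold (log2 3.25 ± 0.37 SE; edgeR adjusted p = 2.36e-06). Among genes of the RhoA pathway, a peak within Diaph1, a formin downstream of RhoA (chromosome 18, 37927616 to 37928315), rose 3.13-fold. Peaks within Mllt3 (3.91-fold), a factor of stem-cell maintenance, Aldh1a1 (4.41-fold), a retinoic-acid enzyme, and Tnfaip3 (4.38-fold), a brake on NF-kB, rose as well. A peak 22623 bp from Mrtfb, an actin-sensing co-activator of SRF, rose 3.59-fold. No loss kept its call under every setting, since 0 of the 710 lower peaks were still called in edgeR with the gene-end share as a covariate, at 61.6% of their median size. Most gains lost their call with it too: 142 of the 2504 higher peaks were still called, at 76.4% of their median size. Under every setting 102 higher peaks kept their call. Of the 78 peaks named by the rule for this comparison, 59 lost their call with the covariate. Losses that held under every left-out library included a peak 49643 bp from Tle3, a Groucho-family co-repressor (chromosome 9, 61321984 to 61322683; 3.04-fold lower, edgeR adjusted p = 6.99e-04), and one within Sorcs2 (3.04-fold lower, edgeR adjusted p = 0.00509). A peak 4085 bp from Mcl1, a survival factor, was 3.13-fold lower and lost its call without young 1 (edgeR adjusted p = 0.0766). At Selp, the weaker of its ends held a peak that fell by 1.54 on the log2 scale, a call that ended without young 1 or aged 3 (edgeR adjusted p from 0.0723 to 0.231). The number of peaks called was 776 without young 1, 2072 without young 2, 1831 without young 3, 6357 without young 4, 1792 without aged 1, 2002 without aged 2 and 1095 without aged 3.

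Of 16 gene lists tested with camera on gene ends, which compares a list with all other genes, 7 passed in aged against young cells. The HSC ageing signature opened (median log2 0.49, adjusted p = 1.39e-09), and it alone held with an estimated correlation between genes (adjusted p = 0.0477). Within it 6 of 28 gene ends rose, and adjusted over the list alone 12 rose and 1 fell. The megakaryocyte and platelet list opened (adjusted p = 7.02e-05; 3 of 19 rose, Gp1ba, Vwf and F2rl2; adjusted over the list alone, 8 rose), with an adjusted p of 0.136 under the estimated correlation. The F2rl2 call ended without young 1, young 2, aged 1, aged 2 or aged 3 (edgeR adjusted p from 0.0550 to 0.201). The HSC identity list opened (adjusted p = 0.00329; 2 of 26 rose, Angpt1 and Hoxb5; adjusted over the list alone, 6 rose), with 0.420 under the estimated correlation and 0.155 without young 1. Angpt1, a ligand of the receptor Tie2, rose 2.13-fold and lost its call without young 1 or aged 3 (edgeR adjusted p from 0.0951 to 0.0956). Hoxb5 rose 2.10-fold and lost its call without young 1, young 2 or aged 3 (edgeR adjusted p from 0.0519 to 0.153). The interferon and antigen presentation list opened (adjusted p = 0.00483; 2 of 27 rose, H2-Eb1 and Ifit2; adjusted over the list alone, 4 rose), with 0.181 under the estimated correlation. Both calls ended without any 1 of young 1, young 2, young 3, aged 1, aged 2, aged 3 or aged 4 (edgeR adjusted p from 0.0544 to 0.279), and DESeq2 called 0 of the 27, of which 8 were higher in edgeR at an unadjusted p under 0.05. The erythroid list opened (adjusted p = 0.0275; 1 of 12 rose; adjusted over the list alone, 3 rose), with 0.420 under the estimated correlation and 0.0508 to 0.0850 without young 1, aged 2 or aged 3. The B and common lymphoid list closed (median log2 -0.38, adjusted p = 0.00131), where 0 of 14 gene ends changed in edgeR or DESeq2, 1 fell at an unadjusted p under 0.05 and 1 fell when adjusted over the list alone. Its adjusted p was 0.136 under the estimated correlation and 0.0707 without young 1. Single peaks near its members did not all close. The 4 members with called peaks of smallest p were higher at Flt3 (2.84-fold), Ebf1 (2.21-fold) and Foxo1 (2.34-fold) and lower at Rag1. The Ebf1, Foxo1 and Rag1 peak calls ended without young 1. The nuclear envelope and heterochromatin list closed (adjusted p = 0.0438; 1 of 27 rose, Kdm4a, and 2 fell, Lmnb1 and Syne2; adjusted over the list alone, 1 rose and 3 fell), with 0.495 under the estimated correlation and 0.0707 to 0.158 without young 1, young 3, aged 1, aged 2 or aged 3. The Syne2 call ended without any 1 young or aged library but young 4 and aged 5 (edgeR adjusted p from 0.0588 to 0.240), and that of Kdm4a without any 1 of these but young 4 (0.0532 to 0.230). By the called peak of smallest p per member, peaks within Syne2 (2.56-fold) and Ehmt1 (2.70-fold) were higher and that at Lmnb1 was lower. These peak calls each ended without young 1. Only 3 lists passed without young 1. The RhoA pathway list did not pass (median log2 -0.15, adjusted p = 0.0855). The endothelial and stromal (adjusted p = 0.0855), myeloid (0.164), SRF and YAP target (0.180), T and NK (0.475), cell cycle (0.695), NF-kB and inflammation (0.741), non-haematopoietic control (0.741) and immediate early and AP-1 (0.801) lists did not pass in camera.

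The share of counts at gene ends was lower in aged than in young libraries, 42.6% ± 4.4 (SD, n = 5) against 48.7% ± 1.9 (SD, n = 4). Adjusted for batch the difference was -5.45 percentage points (2-sided exact permutation within batches over 36 arrangements, p = 0.0278, the smallest these allow; over all 126 arrangements, p = 0.0476). It was -7.74 in batch 1, -6.08 in batch 2 and -1.13 in batch 3, which holds 1 library of each group. Aged 5, the aged library of batch 3, had a share of 49.6%, above that of young 1 (47.0%) and young 2 (47.0%). Without any 1 library it lay between -6.75 and -4.43, where the exact permutation p was 0.0556 to 0.167. Peaks in gene spans took 31.2% ± 2.2 of aged and 28.1% ± 1.0 of young counts, and intergenic peaks 26.2% ± 2.2 and 23.2% ± 0.94 (SD). Gene ends made up 24.4% of all peaks tested, 5.63% of the peaks that rose and 31.3% of those that fell. Scaled over all peaks, gene ends were thus scarce among gains, unlike in the test scaled over gene ends alone, where most calls were gains.

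**Figure D2:**
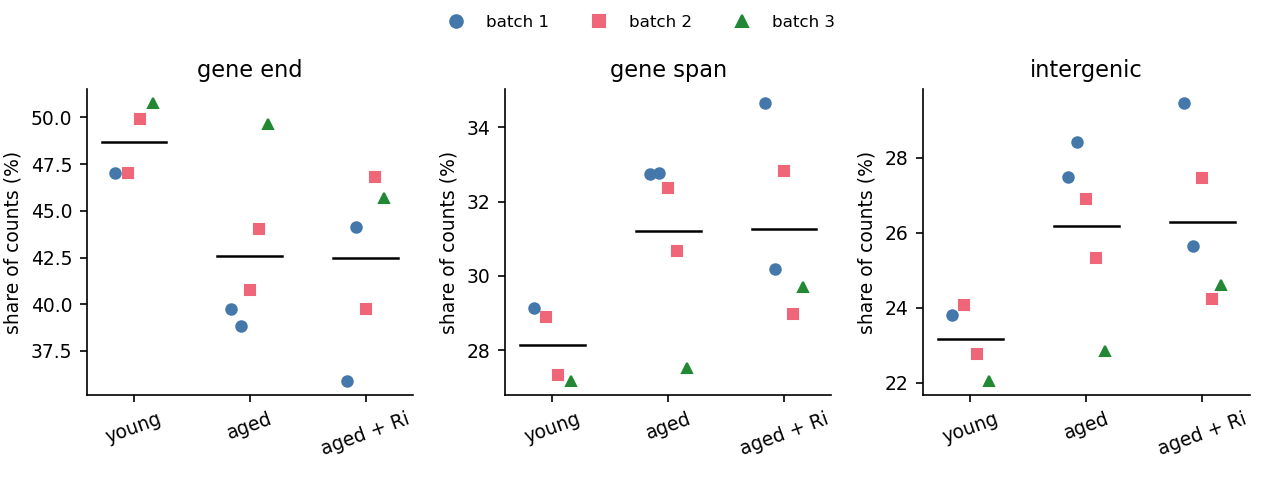
Share of each library's counts (%) in peaks at gene ends, in gene spans and between genes, with dots coloured by sequencing batch and a black line at each group mean. The gene-end share averaged 48.7% in young, 42.6% in aged and 42.5% in aged Ri libraries.

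The second comparison asked what RhoA inhibition changes in aged LT-HSCs. Ri-treated cells gained accessibility at Slc37a3, a sugar-phosphate exchanger family member, at Cyp1b1, a cytochrome P450 of xenobiotic metabolism, and at the stress genes Atf3 and Nqo1. At the end of Slc37a3 (chromosome 6, 39334050 to 39334749) the signal rose from 24.0 ± 7.45 (SD, n = 5) to 75.0 ± 30.8 (SD, n = 5) CPM, 2.98-fold (log2 1.58 ± 0.24 SE; edgeR adjusted p = 0.00230). Cyp1b1 (chromosome 17, 79715447 to 79716146) rose 2.55-fold (log2 1.35 ± 0.23 SE; edgeR adjusted p = 0.00790) and Atf3 (chromosome 1, 191183049 to 191183748) 2.40-fold (log2 1.26 ± 0.22 SE; edgeR adjusted p = 0.0254). Iqgap2, a scaffold that binds Rac and Cdc42, lost accessibility at its end (chromosome 13, 95892021 to 95892720), 1.79-fold lower (edgeR adjusted p = 0.0332).

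In all, 10 of 13239 gene ends changed in edgeR, 8 upward and 2 downward, and 889 had an unadjusted p under 0.05. Besides those above, Pdgfb (2.45-fold), a platelet-derived growth factor, Nqo1 (2.24-fold), a quinone reductase, and Klf2 (1.87-fold), a flow-responsive transcription factor, rose. Gprc5a (chromosome 6) and Ass1 (chromosome 2) rose by log2 1.02 and 0.79 and were named after their values were seen. Cep70, a centrosome protein (chromosome 9, 99182090 to 99183799), was 1.63-fold lower (edgeR adjusted p = 0.0194), which brought it from 166 ± 41.9 (SD, n = 5) in aged to 102 ± 27.3 (SD, n = 5) CPM, against 79.7 ± 30.4 (SD, n = 4) in young. The aged and aged Ri libraries of the same number deviated together, with batch not removed, and each such pair also shares a batch. With the number as a block 139 gene ends changed, 103 upward and 36 downward, including all 10. Only Slc37a3 kept its call under every left-out library, and with the 2 kb window it was not called (log2 0.23, edgeR adjusted p = 0.934). Cyp1b1 lost its call without aged 2, aged 3, aged 4 or aged Ri 3 (edgeR adjusted p from 0.0516 to 0.0654). Pdgfb lost it without aged 1, aged 2, aged 3, aged 4 or aged Ri 3 (0.0501 to 0.232), and Nqo1 without aged 2, aged 3, aged 4, aged 5 or aged Ri 2 (0.0516 to 0.102). Atf3 lost it without aged 1, aged 2, aged 3, aged 4, aged Ri 2, aged Ri 3 or aged Ri 5 (0.0550 to 0.128), and Klf2 without aged 1, aged 2, aged 3, aged 4, aged Ri 2, aged Ri 3 or aged Ri 4 (0.0567 to 0.135). Iqgap2 lost it without aged 2, aged 3, aged 4, aged 5, aged Ri 1, aged Ri 3 or aged Ri 5 (0.0956 to 0.155), and Cep70 without aged 1, aged 2, aged 3, aged 4, aged Ri 4 or aged Ri 5 (0.0595 to 0.121). The count was 1 without aged 2, aged 3 or aged 4, 3 without aged Ri 3, 5 without aged 1, 16 without aged Ri 2, 18 without aged 5 and 25 without aged Ri 4. Rhoa itself did not pass (log2 -0.11, edgeR adjusted p = 0.962), nor did Kit (log2 -0.22, edgeR adjusted p = 0.883), Klf4 (log2 0.23, edgeR adjusted p = 0.883), Procr (log2 0.52, edgeR adjusted p = 0.593), Selp (log2 0.34, edgeR adjusted p = 0.948) or Vwf (log2 -0.49, edgeR adjusted p = 0.846).

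**Figure D3:**
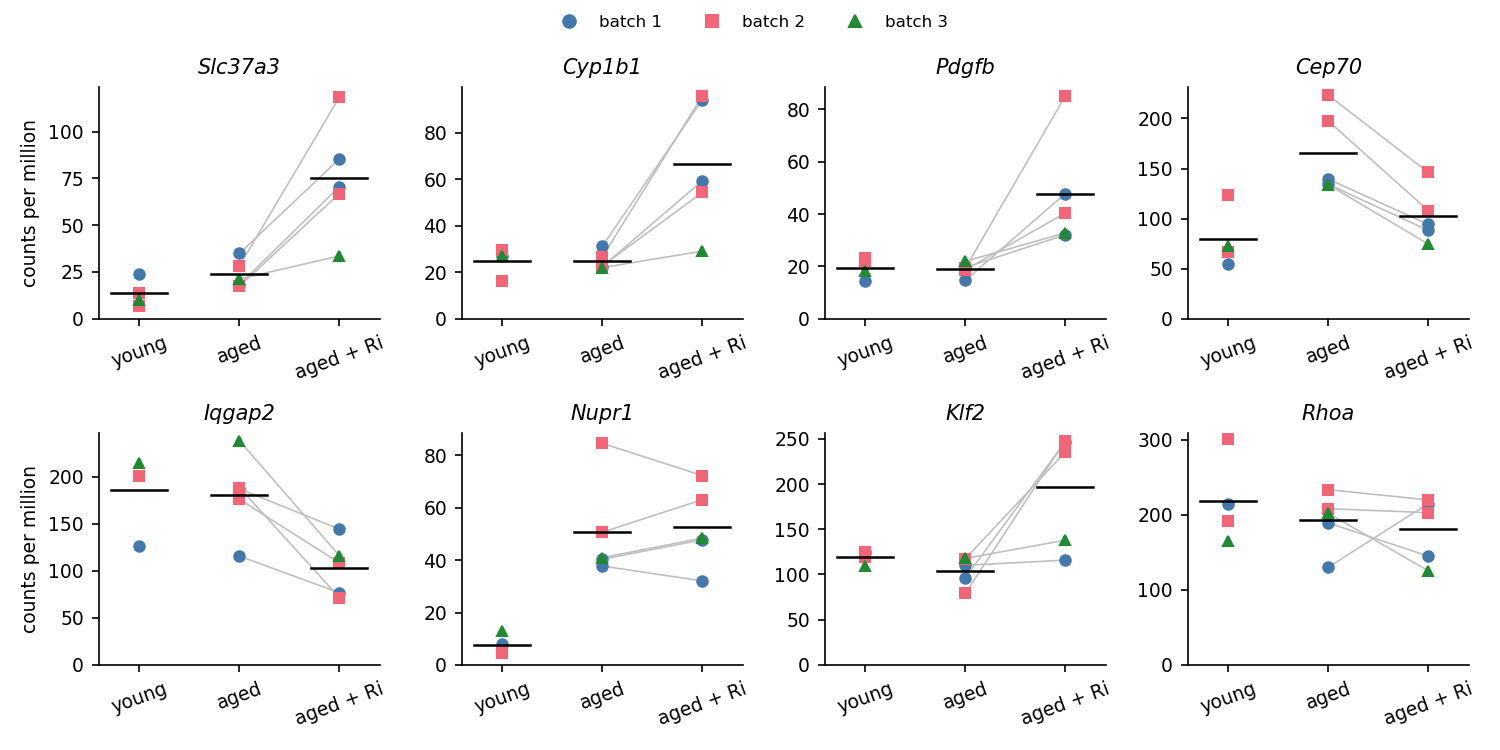
CPM (TMM-scaled, linear axis) at the gene ends of 8 genes in each library, with lines joining the aged and aged Ri libraries of the same number and a black line at each group mean. Slc37a3 averaged 13.6 in young, 24.0 in aged and 75.0 in aged Ri libraries.

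Of those tested, 0.446% of peaks and 0.0755% of gene ends were called after Ri, against 5.72% and 2.10% with age. The difference between peaks and gene ends was not tested. In edgeR 251 of 56235 peaks changed, 211 upward and 40 downward. With the block 2289 changed, 1548 upward and 741 downward, including all 251. Among peaks that met the naming rule, the largest gain was within Baiap2, which encodes an adaptor between Rac, Cdc42 and the actin cytoskeleton (chromosome 11, 119975687 to 119976386; 4.14-fold, log2 2.05 ± 0.33 SE, edgeR adjusted p = 0.00270). A peak within Sptb, which encodes the membrane-skeleton protein beta-spectrin (chromosome 12, 76593731 to 76594430), rose 3.53-fold (edgeR adjusted p = 0.00397). Peaks within Stn1 (3.51-fold), a telomere-capping protein, 7934 bp from Asgr2 (3.43-fold), a lectin receptor, 6734 bp from Ripk3 (3.05-fold), a necroptosis kinase, and 1717 bp from Arid5a (3.03-fold), an RNA-stabilising protein, rose as well. A peak within Medag (chromosome 5, 149428292 to 149428991) was 2.61-fold lower (edgeR adjusted p = 0.00469). These 7 peaks kept their calls under every left-out library. A peak within Flna, an actin cross-linker, rose 2.22-fold, and its call ended without aged 1, aged 3, aged 4, aged Ri 2 or aged Ri 3 (edgeR adjusted p from 0.0786 to 0.145). Gene ends made up 6.16% of the peaks that rose. The count of peaks was 91 without aged 1, 53 without aged 2, 38 without aged 3, 26 without aged 4, 60 without aged Ri 2, 13 without aged Ri 3 and 496 without aged Ri 5.

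Of the 16 lists, 2 passed in camera on gene ends after Ri, and neither held with an estimated correlation. The immediate early and AP-1 list opened (median log2 0.18, adjusted p = 8.00e-04; with the block, 4.81e-05). In it Atf3 and Klf2 rose, 2 of 24, and 3 adjusted over the list alone; with the estimated correlation its adjusted p was 0.316, and without aged Ri 2 it was 0.109. The megakaryocyte and platelet list closed (median log2 -0.20, adjusted p = 0.00592; with the block, 0.00220), with 0 of 19 gene ends called in edgeR or DESeq2 and 1 lower at an unadjusted p under 0.05. Its adjusted p was 0.316 with the estimated correlation, 0.475 on peaks within 50 kb, and 0.0680 to 0.0991 without aged 3 or aged Ri 4. The number of lists that passed was 1 without aged Ri 2 and 4 without aged 5. The RhoA pathway (median log2 0.04, adjusted p = 0.376), SRF and YAP target (0.771), HSC identity (0.533), HSC ageing signature (0.109), NF-kB and inflammation (0.109), myeloid (0.0907), cell cycle (0.236) and T and NK (0.283) lists did not pass. Nor did the B and common lymphoid (0.533), nuclear envelope and heterochromatin (0.533), erythroid (0.746), endothelial and stromal (0.771), non-haematopoietic control (0.771) and interferon and antigen presentation (0.851) lists. The gene-end share of counts differed by -0.14 percentage points between aged Ri (42.5% ± 4.5, SD, n = 5) and aged libraries (2-sided exact permutation within batches, p = 0.972; 0.73 in batch 1, 0.89 in batch 2 and -3.94 in batch 3). Without any 1 library it ran from -1.55 (without aged Ri 2) to 1.00 (without aged Ri 1), a change of sign.

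The third comparison set Ri-treated aged cells against young cells, and asked which differences from young cells were present after treatment. Nupr1 was 6.06-fold higher in aged Ri than in young cells (log2 2.60 ± 0.29 SE; edgeR adjusted p = 2.53e-07), Cavin2 4.96-fold (log2 2.31 ± 0.24 SE; edgeR adjusted p = 2.35e-07) and Wwtr1 3.83-fold (log2 1.94 ± 0.21 SE; edgeR adjusted p = 8.06e-07). Slc37a3, the gene end most changed by Ri, was 4.74-fold higher. Procr, which encodes the stem-cell surface receptor EPCR, was 2.09-fold higher (25.3 ± 7.84, SD, n = 4, in young and 55.7 ± 18.8, SD, n = 5, in aged Ri libraries; edgeR adjusted p = 0.00580), and its call ended without aged Ri 3 (0.0531).

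Across gene ends 689 of 13239 differed in edgeR, 530 higher and 159 lower in aged Ri cells, and 2889 had an unadjusted p under 0.05. Gpr183 (4.55-fold) and Plscr1 (2.64-fold) were higher, as was Lrtm2 (5.77-fold), a leucine-rich repeat membrane protein, whose 500 bp window left no difference (log2 -0.01). No lower gene end kept its call under every setting. Tifab, an inhibitor of TRAF signalling, was 2.29-fold lower (edgeR adjusted p = 7.61e-04), a call that ended without young 1 and young 3 together (0.0961) and with the gene-end share as a covariate (0.179). Cabp1, a calcium-binding protein, was 2.25-fold lower until young 1 was left out (edgeR adjusted p = 0.0736). Rag1, the lymphoid recombinase, was 3.32-fold lower, a call that ended without young 1, young 3, aged Ri 1 or aged Ri 3 (edgeR adjusted p from 0.0558 to 0.155). Vwf (2.03-fold, edgeR adjusted p = 0.0780), Selp (2.25-fold, edgeR adjusted p = 0.0920), Kit (log2 -0.17, edgeR adjusted p = 0.537), Klf4 (log2 -0.06, edgeR adjusted p = 0.862) and Rhoa (log2 -0.24, edgeR adjusted p = 0.370) did not pass. The count was 212 without young 1, 339 without young 2, 393 without young 3, 1041 without young 4, 403 without aged Ri 1, 1079 without aged Ri 2, 244 without aged Ri 3, 1191 without aged Ri 4 and 373 without aged Ri 5. Of the peaks 6443 differed, 4441 higher and 2002 lower. The count was 3738 without young 1, 4042 without young 2, 4065 without young 3 and 2809 without aged Ri 3. A peak 41090 bp from Pde4b, a cyclic-AMP phosphodiesterase, was 8.81-fold higher. A peak 30417 bp from Spry1, an inhibitor of receptor signalling, was 3.39-fold lower (edgeR adjusted p = 1.79e-04; with the gene-end share as a covariate, 0.177). With that covariate, 13 of the 2002 lower and 517 of the 4441 higher peaks were still called in edgeR. The lower peaks kept 66.5% and the higher peaks 78.9% of their median log2 size, with larger standard errors.

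Against young cells 7 lists passed in camera. The HSC ageing signature was more open (median log2 0.63, adjusted p = 3.34e-11; 9 of 28 gene ends higher; adjusted over the list alone, 16), and it alone held with an estimated correlation (adjusted p = 0.0293). The immediate early and AP-1 list was more open (adjusted p = 0.0210; 4 of 24 higher, Atf3, Ier3, Egr3 and Klf2; adjusted over the list alone, 7; estimated correlation, 0.385; without aged Ri 2, 0.0952). The Ier3 call ended without young 1 (edgeR adjusted p = 0.0611) and that of Egr3 without aged Ri 5 (0.0572). That of Klf2 ended without young 1, young 2, young 3 or aged Ri 3 (0.0664 to 0.0931). The interferon and antigen presentation list was more open (adjusted p = 0.0210; 2 of 27 higher, H2-Eb1 and Rsad2; adjusted over the list alone, 3; estimated correlation, 0.367). The H2-Eb1 call ended without young 1, young 2, aged Ri 1 or aged Ri 5 (edgeR adjusted p from 0.0579 to 0.164) and that of Rsad2 without young 2, young 4, aged Ri 1, aged Ri 3 or aged Ri 5 (0.0670 to 0.159). The nuclear envelope and heterochromatin list was more closed (adjusted p = 0.0210; estimated correlation, 0.416; 0.0612 to 0.101 without young 1, aged Ri 1 or aged Ri 5), with 0 of 27 gene ends called in edgeR or DESeq2, and 2 higher and 9 lower at an unadjusted p under 0.05. The called peaks of its 4 members of smallest p, Banf1, Sun1, Ehmt1 and Lmnb1, were higher. The Lmnb1 peak call ended without young 1, young 3 or aged Ri 3 (edgeR adjusted p from 0.0522 to 0.0742). The B and common lymphoid list was more closed (adjusted p = 0.0225; Rag1 alone lower of 14; estimated correlation, 0.367; 0.0748 to 0.262 without young 1 or aged Ri 2). The HSC identity list was more open (adjusted p = 0.0412; Procr, Tek, Hoxb5 and Angpt1 higher, 4 of 26; adjusted over the list alone, 9; estimated correlation, 0.423; 0.0507 to 0.401 without young 1, young 3 or aged Ri 1). The Tek call ended without aged Ri 5 (edgeR adjusted p = 0.0545), that of Hoxb5 without young 1, young 2, aged Ri 1 or aged Ri 3 (0.0525 to 0.150), that of Angpt1 without young 1, young 2, young 3, aged Ri 3 or aged Ri 5 (0.0522 to 0.124) and that of Procr without aged Ri 3 (0.0531). The megakaryocyte and platelet list was more open (adjusted p = 0.049995; 1 of 19 higher, Gp1ba; adjusted over the list alone, 6; estimated correlation, 0.385; 0.0604 to 0.295 without young 1, young 3, aged Ri 1, aged Ri 2, aged Ri 3 or aged Ri 5). The Gp1ba call ended without young 3, aged Ri 1, aged Ri 3 or aged Ri 5 (edgeR adjusted p from 0.0637 to 0.108). The number of lists that passed was 3 without young 1 and 4 without aged Ri 1. The erythroid (adjusted p = 0.0646), endothelial and stromal (0.142), NF-kB and inflammation (0.142), cell cycle (0.142), SRF and YAP target (0.169), RhoA pathway (0.368), non-haematopoietic control (0.605), T and NK (0.924) and myeloid (0.924) lists did not pass. The gene-end share differed from that of young libraries by -5.72 percentage points (2-sided exact permutation within batches, p = 0.0833; over all arrangements, p = 0.0397), with -7.01 in batch 1, -5.20 in batch 2 and -5.07 in batch 3.

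The last question was whether Ri moved aged chromatin back toward the young state. At the 3214 peaks changed by age, 63.2% moved back after Ri, and the log2 changes by age and by Ri had a correlation of -0.14 across peaks, which are not independent replicates. Both comparisons share the aged libraries, whose noise enters them with opposite signs. In the planned simulation, which kept the aged libraries and drew aged Ri libraries from their fitted mean, 48.7% moved back with a correlation of -0.02 and a covariance of -0.00237. That mean carries the noise of the aged libraries, so this version leaves out what they share. With all libraries redrawn and no effect of Ri, a version made after the first was seen, 66.7% moved back, with a correlation of -0.24. The covariance was -0.0425 simulated against -0.0250 observed. The 10 sets behind the 66.7% called 8799 to 9366 peaks for age, against 3214 in the real data. The simulated and observed shares thus rest on unlike sets of peaks. The simulated libraries carry no pairing, which in the real ones would lessen the chance return. With the aged libraries split between the comparisons, the mean over 10 splits was 50.9% (21.6% to 79.6%) and the mean correlation 0.06 (-0.25 to 0.38), where aged Ri libraries could share a pair with the ageing side. With each pair kept in the treatment comparison the means were 51.5% (41.9% to 66.7%) and 0.01 (-0.05 to 0.06). Without aged 3, 53.7% moved back, without aged 5, 78.7%, without aged Ri 3, 72.9% and without aged Ri 4, 51.4%, and the correlation was -0.08 without aged 3, -0.28 without aged 4, -0.33 without aged 5, -0.31 without aged Ri 3, -0.02 without aged Ri 4 and -0.04 without aged Ri 5. Of the peaks changed by age, 69.0% still differed from young cells after Ri in the same direction. Both comparisons share the young libraries. With aged Ri libraries simulated from the young mean the share was at most 0.0112%, in sets with 8849 to 9163 peaks called for age. With the young libraries split the share ran from 6.17% to 83.7% over 6 splits, with 2 young libraries on each side. Among the peaks called in both comparisons, 18 rose with age and fell with Ri, where 1.78 would be shared by independent lists. With the Ri calls of the block it was 174 against 33.0. A further 5 fell with age and rose with Ri, against 2.66. The aged libraries enter both lists with opposite signs. The 10 sets simulated with no effect of Ri had at most 1 Ri call each in edgeR, with 0 peaks that rose with age and fell with Ri and, in 1 set, 1 peak that fell and rose. With the aged libraries split, at most 19 peaks were called for Ri, too few to repeat the count. The simulated value leaves out the effects and the value of independent lists the shared libraries, so the excess over either is not read as an effect of Ri on ageing changes. The 18 included peaks near Bcl2, a survival factor, Gfi1b, a transcriptional repressor active in megakaryocyte and erythroid cells, and Hint1, and a peak within Ctnnd2. The Ri calls of these 4 peaks ended without any 1 of aged 1, aged 2, aged 3, aged 4, aged Ri 2 or aged Ri 3, and some also without aged Ri 1, aged Ri 4 or aged Ri 5 (edgeR adjusted p from 0.0517 to 0.316). A further 8 peaks rose with both, where 9.40 would be shared by independent lists. On an ageing axis scored in each library from peaks called without it, aged libraries averaged 0.82 ± 1.03 (SD, n = 5), young -0.80 ± 0.57 (SD, n = 4) and aged Ri libraries 0.45 ± 0.53 (SD, n = 5). Aged 5 lay at -0.58, on the young side of young 4 (-0.12). The peaks scored differed by library, from 715 higher and 61 lower (young 1) to 4073 and 2277 (young 4). Aged and young differed by 1.58 after adjustment for batch (2-sided exact permutation within batches, p = 0.0556; over all arrangements, p = 0.0317). Aged Ri and aged libraries differed by -0.37 (2-sided exact permutation within batches, p = 0.472), with Ri lower in 4 of 5 pairs, all but that of aged 5 (exact paired permutation p = 0.313, smallest possible 0.0625). The difference was -0.05 without aged 3, -0.12 without aged Ri 4, -0.62 without aged 4 and -0.65 without aged 5 or aged Ri 5. With the aged library of the same number left out as well, the difference was 0.04. In a planned setting that scored 500 peaks each way, it was -0.08 (2-sided exact permutation within batches, p = 0.806). The -0.37 thus depends on which peaks were scored. Aged Ri libraries stayed 1.26 above young ones (2-sided exact permutation within batches, p = 0.0278, the smallest possible), and without any 1 library the exact permutation p was 0.0556 to 0.167. With the paired aged library left out the difference was 1.64, which no longer passed (2-sided exact permutation within batches, p = 0.0556).

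**Figure D4:**
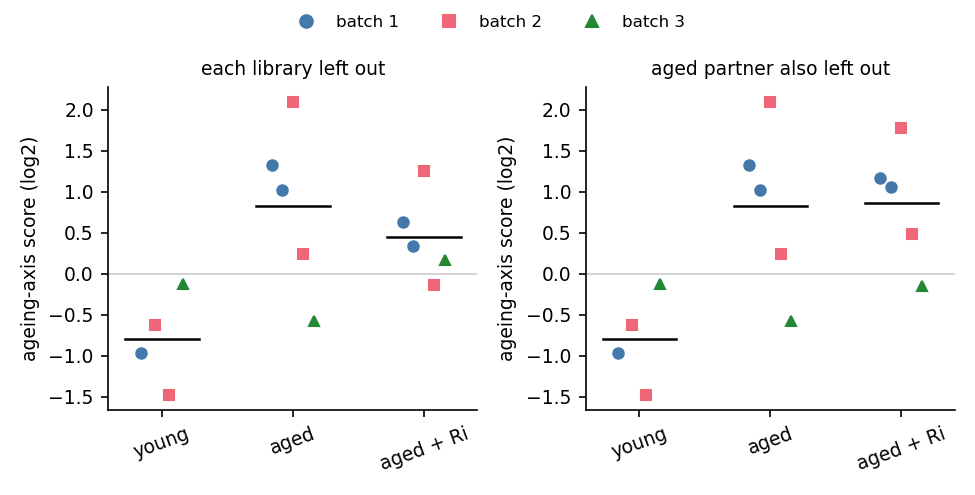
Position of each library on the ageing axis (0 and below toward young, above 0 toward aged; no unit), scored from peaks called without that library, and again for aged Ri without the aged library of the same number, with dots coloured by batch and a black line at each group mean. Aged Ri libraries averaged 0.45 by the first score and 0.87 by the second.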

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

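The tests for far libraries, the other splits into groups, the model with library size, the covariate, the swap, the redrawn simulation and the split with the pairs kept were chosen after the result they measure was seen, while the batch-adjusted share difference, the peak count without young 4 and the simulation that kept the aged libraries were planned. Among 96 groups of 4 or 5 libraries, 6 held a library far from the others of its group (Dixon's gap test), where chance gives about 1 in 20 groups. On the second principal component, aged Ri 1 lay at 64.5 and the other aged Ri libraries at -38.7 to -14.8. At gene ends, in CPM, Nupr1 was 84.6 in aged 3 (other aged libraries 37.7 to 50.7), Gpr183 10.97 in aged 5 (others 32.0 to 40.5), Atf3 98.7 in aged 5 (others 52.4 to 65.7), Procr 88.6 in aged Ri 3 (others 42.0 to 52.9) and Iqgap2 127 in young 1 (others 201 to 215). With 6 of 96 groups, these are about as many as chance gives.

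Other splits of the libraries into groups of the same sizes were drawn, 50 of 126 per comparison with the real one included. For aged against young, 2 of 50 splits called as many peaks (real 3214, highest other 4250), 2 as many gene ends (278; 289) and 2 as many lists (7; 10). Each share lies under 0.05, but another split called more than the real groups each time, so chance is not excluded. For aged Ri against aged, 1 of 50, the real one, called as many peaks (251; 18) and 1 as many gene ends (10; 5), while 25 of 50 passed as many lists (2; 11), so for the 2 lists chance was not excluded. Of the 4 other drawn splits that also part all 5 pairs, the highest called 0 peaks in edgeR. These splits are too few for a share under 0.05. For aged Ri against young it was 1 of 50 for peaks (6443; 5495), 2 for gene ends (689; 1223) and 1 for lists (7; 6). Each share lies under 0.05, but the exchange of young 4 and aged Ri 4 came near the real peaks and passed the real gene ends. These counts therefore do not exclude chance. With the block, the 16 arrangements are too few for a share under 0.05 (real 2289 peaks, highest other 353; real 139 gene ends, highest other 19; 1 of 16 for both).

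The lower share of counts at gene ends in aged libraries was weighed first. Batch was argued against, since the batch-adjusted difference was -5.45 percentage points and each of the 3 batches gave a lower share. Library size was argued against too, with a difference of -5.20 ± 1.59 (SE) once the log2 total was in the model. A library-wide trend, such as a difference in signal over background, may underlie many of the peaks called with age: with the gene-end share as a covariate, these peaks kept 74.1% of their median size, from 1.27 (median SE 0.32) to 0.94 (0.38) on the log2 scale, and 142 of 3214 kept their call, as the size fell and the error grew. The share follows the groups in all but aged 5 (49.6%, above young 1 and young 2), so this trend and ageing cannot be told apart for most libraries, and ageing stays open, untested.

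The split that called more peaks than the real groups exchanged young 4 and aged 4 (4250 against 3214), and the next highest called 91. A swap of the 2 libraries was argued against: aged 4 lay nearer the other aged libraries at 88.2% of gene ends called without it, and young 4 nearer the aged ones at 31.0%. The exchange leaves batch 3 without a library of the young side, so batch 3 enters the contrast only through the aged Ri libraries, which the fit includes. Without young 4 the real groups called 6357 peaks. Such a count points to a structure of the samples, in which the batch 3 libraries differ less by age, or in the reverse order. Aged 5 lay nearer the aged libraries at 29.7% of gene ends called without it, against 31.0% for young 4. On the ageing axis aged 5 (-0.58) lay on the young side of young 4 (-0.12). Neither an exchange of young 4 and aged 5 nor a biological explanation was tested for this structure.

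The partial return of ageing changes after Ri was weighed last. The aged libraries shared by both comparisons may account for it: with all libraries redrawn and no effect of Ri, the mean correlation was -0.243, against -0.14 observed. Redrawn sets called 8799 to 9366 peaks for age, against 3214 in the real data, so the sizes of the simulated and observed return are not compared. The planned simulation gave -0.02, but it draws aged Ri libraries from a mean that carries the noise of the aged ones, so it leaves out the noise they share. With the aged libraries split between the comparisons and the pairs kept, the mean correlation was 0.00780, and 4 of 10 splits were negative (-0.05 to 0.06). A small effect of Ri toward or away from the young state stays open.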

How the results depend on the processing

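Leaving out young 1 and young 3, the gene-end share as a covariate, the ageing score without the paired aged library, the split of aged libraries with the pairs kept, and left-out libraries for lists, shares, totals, reversal and the score were chosen after seeing the data. Where no construction is named, the cause was not tested.

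For aged against young, the 3214 peaks became 1808 without the batch term, 278 without young 1 and young 3 (fewer libraries) and 145 with the gene-end share as a covariate. The other settings gave 2717 (limma voom) to 3528 (library size alone). The 278 gene ends became 80, 11 and 12 under the same 3 settings, and the 7 lists became 1 with the estimated correlation and 3 without young 1 and young 3. For aged Ri against aged, the 251 peaks became 51 without the batch term, 819 with the 2 groups alone and 762 without young 1 and young 3. The 10 gene ends became 3 without the batch term, 27 without young 1 and young 3 and 76 with the covariate. The 2 lists became 0 with the estimated correlation and 1 on peaks within 50 kb. For aged Ri against young, the 6443 peaks became 4204 without the batch term, 4217 with limma voom, 1555 without young 1 and young 3 and 559 with the covariate. The 689 gene ends became 336 without the batch term, 102 without young 1 and young 3 and 37 with the covariate, and the 7 lists became 1 with the estimated correlation and 3 without young 1 and young 3. Cyclic loess offsets gave 4172 higher and 2828 lower peaks there, against 4441 and 2002.

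With the replicate block, the paired comparison of aged Ri with aged called 2289 peaks and 139 gene ends. Young libraries share only a number with the others, and no young library correlated best with its own number, while of the aged libraries 1, aged 1, did. There the block gave 3469 peaks (1719 higher, 1750 lower) and 860 gene ends for aged against young, and 3795 peaks and 2 lists for aged Ri against young. In the paired comparison the block changed no other call of a list or share.

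Without each library in turn, peaks called ran from 776 (without young 1) to 6357 (without young 4) for aged against young, from 13 (without aged Ri 3) to 496 (without aged Ri 5) for aged Ri against aged, and from 2809 (without aged Ri 3) to 9036 (without young 4) for aged Ri against young. Gene ends ran from 30 (without young 1) to 662 (without aged 5), from 1 (without aged 2, aged 3 or aged 4) to 25 (without aged Ri 4), and from 212 (without young 1) to 1191 (without aged Ri 4). Lists ran from 3 (without young 1) to 8 (without aged 5), from 1 (without aged Ri 2) to 4 (without aged 5), and from 3 (without young 1) to 8 (without aged Ri 4). Of the called peaks, 619 of 3214, 13 of 251 and 1971 of 6443 kept their call under every left-out library, and 102, 12 and 422 under every setting. For gene ends these were 26 of 278, 1 of 10 and 134 of 689, and 7, 0 and 23.

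The gene-end share in aged less young libraries lay between -6.75 (without young 4 or aged 5) and -4.43 percentage points (without young 1), and no longer passed, since fewer libraries allow fewer arrangements. For aged Ri against young it was -6.22 and passed by permutation over all libraries (exact permutation p = 0.0397). Totals passed in no comparison, with or without a library left out. Their differences ran from -113124 to 371624 (aged less young, a change of sign), from 189023 to 669115 (aged Ri less aged) and from 300364 to 859114 counts (aged Ri less young). The share of ageing peaks moved back was 50.9% with the aged libraries split, and 51.4% (without aged Ri 4) to 78.7% (without aged 5) otherwise. With the pairs kept it was 51.5%. Its correlation averaged 0.0617 over the splits (-0.247 to 0.376) and 0.00780 with the pairs kept (-0.0466 to 0.0584), with splits of both signs, and ran from -0.328 (without aged 5) to -0.0172 (without aged Ri 4). The ageing score of aged Ri less young libraries was 1.64 without the paired aged library (exact permutation p = 0.0556) and 0.939 (without aged Ri 3) to 1.55 (without young 4 or aged Ri 5) with a library left out.

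Among named genes, mostly uncalled log2 changes reversed. Kit gene end, aged vs young, was -0.0688 with the covariate and -0.0625 (without aged 3) to 0.15 (without aged 5). Rhoa was 0.14 without young 1 and young 3 and 0.25 with the covariate, and after Ri ran from -0.22 (without aged 2) to 0.0300 (without aged 5). With the 2 kb window, Selp gene end, aged vs young, was -0.524, and Selp was -0.16 after Ri and -0.68 in aged Ri against young. The call of Lrtm2, aged Ri against young, went to -0.0104 with the 500 bp window. Against young, aged Ri gave 0.0374 for Kit, 0.11 for Klf4 and 0.0293 for Rhoa without young 1 and young 3, and 0.22 for Klf4 and 0.14 for Rhoa with the covariate. Klf4 ran from -0.17 (without young 2) to 0.0676 (without young 3). The Tcf7 peak, aged against young, was 0.0521 without young 1 and young 3.

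Motif scores, with and without matching, were not run, since no genome sequence was used here. At these depths most 1.5-fold changes of single peaks go uncalled: 6%, 2% and 0% were recovered in simulated data for the 3 comparisons.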

Other observations

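The hypotheses in this part were set after the response to Ri was seen, and the 4 added lists were written then, while the SRF and YAP list was fixed earlier. Since Cyp1b1 and Nqo1 opened after Ri, 5 hypotheses on the response were tested with camera on gene ends and on peaks within 50 kb, for aged Ri against aged.

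Opening of aryl hydrocarbon receptor targets is a candidate explanation. The adjusted p was 0.0735 at 4 gene ends, all 4 of them higher, and 1.69e-04 at 13 peaks of 6 genes. With the estimated correlation the peaks gave 0.00758, and with the block 1.01e-04. Only 1 of the 13 peaks was called, at Ahrr (chromosome 13, 74259964 to 74260663; log2 1.53, edgeR adjusted p = 7.41e-04), so the list result leans on few genes. Cyp1b1, itself a target, is not in the list. Whether the compound or the loss of RhoA activity would act on the receptor was not tested, and no other inhibitor was used.

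Opening of NRF2 targets may take part, with an adjusted p of 0.607 at gene ends and 0.0237 at peaks, but 0.323 at peaks with the estimated correlation, so it stays open. For closing of SRF and YAP targets, camera gave 0.771 at gene ends and 0.119 at peaks, 2-sided values that do not speak for closing. The called peaks of smallest p at its members, within Flna (log2 1.15) and Wwtr1 (log2 1.21), were higher. Both calls ended without aged 3, aged 4, aged Ri 2 or aged Ri 3. Integrated stress response genes gave 0.607 and 0.435, and heat shock genes 0.0735 and 0.113. None of these 3 lists passed, which leaves the 3 hypotheses open.

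The added lists were also tested at gene ends against young cells. In aged cells the adjusted p was 0.226 for NRF2 targets, 0.203 for aryl hydrocarbon receptor targets, 0.00959 for the integrated stress response (more open; 0.0743 with the estimated correlation) and 0.162 for heat shock. In aged Ri cells these were 0.194, 0.0142 (more open), 0.0142 (more open) and 0.828, all with the preset correlation between genes. The integrated stress response list holds Nupr1, which the ageing list holds too.

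At gene ends called with age in the absence of the library scored, aged 5 lay nearer the aged libraries at 29.7%, against 88.2% to 100% for the other aged libraries. For young libraries the values were 6.67%, 37.9%, 12.1% and 31.0%, and for aged Ri libraries 94.1%, 80.7%, 97.8%, 78.0% and 62.5%.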
